A study of Mus musculus with 6 samples.

How the data were processed

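RNA was extracted with Trizol from duodenum of 3 Apc+/- and 3 Apc+/-Atg7-/- mice, and biotinylated cDNA made from it was hybridised to Affymetrix whole-transcript arrays, per the labels' protocols. The deposited table gives 1 value per probe set and array. RMA and Partek are named, without versions or settings, per the submitters' processing notes. The values run from 2.4 to 13.3 with array medians near 6.5, and were taken as the log2 values that the authors deposited after RMA. The log base is not given in the sources used here and was read from that range. RMA as usually run corrects background and equalises the probe signals of arrays before it summarises them per probe set. Array signal compresses differences of dim and of very bright transcripts, and such equalising removes a shift shared by all transcripts of an array. Scanner files, detection calls, hybridisation dates and batches were not used here, so no batch term could be fitted.

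Probe sets were named through the platform annotation supplied with the series. Of 28853 probe sets, 23410 are in that annotation, 21789 (75.5%) with 1 gene symbol and 1621 with several, and 5443 are not listed in it and were left unnamed. Symbols were checked through gene identifiers against the RefSeq gene table of mouse assembly GRCm38.p6, in which 19855 of the 19938 genes were found, and 0 symbols changed. Where a gene had more than 1 probe set (999 genes), the probe set with the highest mean over all 6 arrays stood for it. No filter on signal was applied and no value was missing. No array was counted as a repeat of another, since the lowest SD of the differences between arrays was 0.213 (log2).

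The genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options, two-sided), as Apc+/-Atg7-/- minus Apc+/-, with Benjamini-Hochberg adjustment over the 19938 genes. The moderated fit had 9.7 degrees of freedom, of which 5.7 came from the shared estimate of variance. The labels give 3 duodena per genotype without naming the animals, so p-values measure the spread between these samples. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1. Levels are means with the SD, and differences are given with limma's standard error.

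The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The 45 lists cover pathways, intestinal and immune cell types, other cells that dissected duodenum could hold, and technical sets, and 1024 of their 1134 entries were measured. Lists with at least 5 measured members, apart from sex-linked genes, were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the 43 lists. Camera with an estimated correlation and fry were alternatives. The text names Atg7 and Apc, and in each direction the 12 largest log2 differences among genes past an adjusted p of 0.05 whose genotypes do not overlap. A direction with fewer than 12 was filled from non-overlapping genes at an unadjusted p under 0.01, given as values that did not pass, and unnamed predicted genes were passed over. From each list it names at most 4 members past an adjusted p of 0.05, and for a called list with fewer than 2 such members the 2 with the smallest p. Other list members appear as examples of counts adjusted over the list alone.

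The alternatives were the replicate number as a block, a further quantile normalization, centring of arrays, eBayes with trend and robust options, a linear model without variance moderation, array weights, removal of the dimmest genes at a looser and a stricter limit, every probe set without naming, the mean of a gene's probe sets, other thresholds, and leaving out each array in turn. All were chosen before the data were examined. On simulated values with the real gene means and SDs, the comparison of 19938 genes recovered 40%, 92%, 96% and 98% of 50 genes each changed by 0.5, 1, 1.5 and 2 (log2), with 6 false among 169 calls. A simulated list shifted by 0.5 was called by camera with either correlation (adjusted p = 1.08e-51 and 0.00373), and 0 of the other lists were called with the preset one. The simulated genes varied independently of each other, so this says nothing about false calls of lists whose genes vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.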

Results

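Gene expression was measured on 6 whole-transcript arrays, 1 per sample, in normal duodenum dissected from Apc+/- mice (n = 3) and Apc+/-Atg7-/- mice (n = 3) of C57Bl6 background. Apc restrains Wnt signalling and is mutated in intestinal adenomas. Atg7 is the E1-like enzyme that autophagosome formation requires. The series' title ties loss of Atg7 to immunity, the microbiome and intestinal tumour growth, and the 6 arrays ask which transcripts differ between the genotypes in duodenum that is not tumour. The deposited values held 28853 probe sets, of which 21789 named 1 gene, giving 19938 genes. Array medians lay between 6.43 and 6.56 (log2), and pairs of arrays correlated across probe sets at r = 0.989 to 0.994. Apc+/- replicate 1 correlated less with Apc+/- replicates 2 and 3 (0.9901 and 0.9909) than with Apc+/-Atg7-/- replicates 1 and 2 (0.9928 and 0.9935). With Apc+/-Atg7-/- replicate 3 it correlated at 0.9894, and it had the lowest array weight (0.417). Array values carry no read depth, and 3 arrays per genotype limit the precision. Apc+/-Atg7-/- replicate 1 came from a male, with a Xist signal of 4.58 and a Y-linked Eif2s3y signal of 8.44, while the other 5 arrays had Xist at 10.1 to 10.3.

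The targeted genes were read first. The Atg7 probe set (10540860) averaged 7.16 ± 0.11 in Apc+/- and 6.63 ± 0.16 in Apc+/-Atg7-/- duodenum (log2, SD, n = 3), and all 3 Apc+/-Atg7-/- arrays lay below all 3 Apc+/- arrays. The difference of -0.53 (SE 0.11) passed when adjusted over the list alone of 30 core autophagy genes (adjusted p = 0.0202), but not over all genes tested (adjusted p = 0.242). The labels do not say which part of Atg7 is deleted, so probes outside it could still find transcript, nor whether the deletion is limited to some cells of the duodenum, such as the epithelium. Apc differed by 0.05 (SE 0.09, adjusted p = 0.991) between groups that carry the same Apc genotype. Besides Atg7, no core autophagy gene passed in either adjustment, and 13 of the 30 were higher and 17 lower, with an adjusted p of 0.415 for the list in limma's camera test. Of 26 measured autophagy receptor and lysosome genes, 0 passed by limma, and the list's median (-0.01) was below 0 while its camera direction was up, at an adjusted p of 0.632.

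Interferon-stimulated genes rose in Apc+/-Atg7-/- duodenum, and 6 of the 14 genes that rose belong to the type I interferon list. Ifit1, which binds foreign RNA, rose 2.23-fold, from 8.67 ± 0.14 to 9.83 ± 0.15 (log2, SD, n = 3, adjusted p = 0.00665). Oasl1, of the oligoadenylate synthetase family, rose 2.17-fold (log2 difference 1.12, SE 0.11, adjusted p = 0.00665). Mx2 rose by 0.94 (SE 0.10, adjusted p = 0.00944), and Rtp4 and Oas1a rose by 0.88 and 0.84 (SE 0.10 for each, adjusted p = 0.0137). Of 28 measured members of the type I interferon list, 6 rose over all genes tested, 24 rose when adjusted over the list alone, and 0 fell in either. The 24 had all 3 Apc+/-Atg7-/- arrays above all 3 Apc+/- arrays, and the median difference over the 28 was 0.69. The list was called by limma's camera test with a preset correlation (adjusted p = 5.19e-54) and not with an estimated one (adjusted p = 0.13 with an estimated correlation), and fry, which asks whether its genes move one way on balance, called it as well (adjusted p = 0.0365).

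Further genes outside that list rose as well, most of them to a similar extent. Ddx60, an interferon-inducible helicase, rose by 1.17 (SE 0.16, adjusted p = 0.0352), Phf11d by 1.14 (SE 0.16, adjusted p = 0.0366) and the ubiquitin ligase Herc6 by 1.02 (SE 0.11, adjusted p = 0.00944). Mlkl, the pseudokinase that executes necroptosis, rose by 0.85 (SE 0.10, adjusted p = 0.0146), and Sass6, a centriole assembly protein, rose by 0.84 (SE 0.10, adjusted p = 0.0137). Akr1b8, an aldo-keto reductase, rose most, 4.34-fold, from 6.20 ± 0.26 to 8.31 ± 0.59 (log2, SD, n = 3, adjusted p = 0.0137). Across all 19938 genes, 14 rose and 8 fell past an adjusted p of 0.05, and in each of these 22 the arrays of the genotypes did not overlap, as was so for 10.04% of all genes against 10% by chance. A small p favours genes whose groups do not overlap, so for the 22 this is no separate evidence. Rnf213 (0.82, SE 0.12) and Xaf1 (0.69, SE 0.10), both with an adjusted p of 0.0366, were named after their values were seen. Xaf1 is on the type I interferon list. Together with Irgm1, given below, they complete the 14. Without the male array 2 genes passed, H2-Ab1 and Itln1, and without Apc+/- replicate 1, Apc+/- replicate 2 or Apc+/-Atg7-/- replicate 3 the counts were 12, 13 and 12. A looser count, of at least 1.5-fold and an unadjusted p under 0.05, gave 42 higher and 64 lower genes (161 in all without the male array). This balance turned to 51 higher and 37 lower without Apc+/-Atg7-/- replicate 3, to 76 and 65 without Apc+/- replicate 1, to 40 and 38 with a variance trend and robust moderation and to 35 and 27 without moderation. In all, 1019 genes lay at an unadjusted p under 0.05 where chance gives 997.

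**Figure D1:**
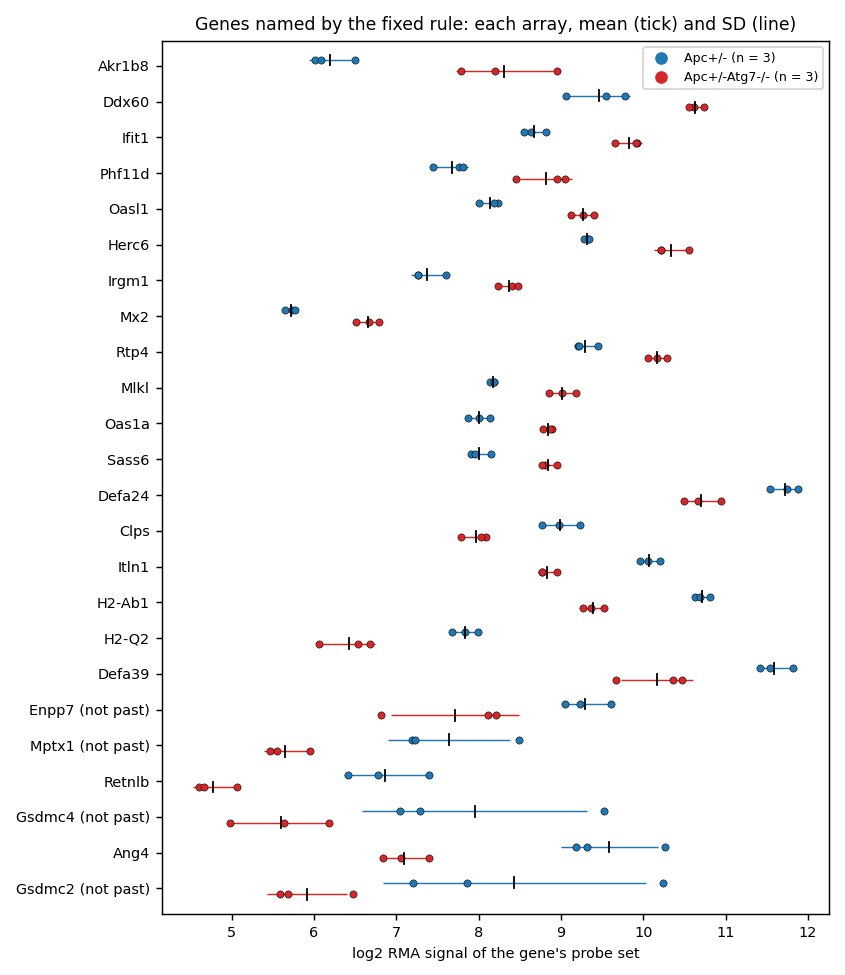
The log2 RMA signal (horizontal axis) of 12 genes per direction, which are the largest differences among genes past an adjusted p of 0.05, filled for lower genes with the largest at an unadjusted p under 0.01, with each array as a point, the group mean as a tick and the SD as a line (n = 3 per genotype). Only genes whose groups do not overlap were eligible, so this holds for all 24 by the rule. The 4 genes marked "not past" had an adjusted p above 0.05.

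Genes of the interferon gamma response and of MHC class I went both ways. Irgm1, an immunity-related GTPase, rose from 7.37 ± 0.20 to 8.37 ± 0.13 (log2, SD, n = 3, adjusted p = 0.0137). H2-Q2, a class I-like gene, fell by 1.41 (SE 0.16, adjusted p = 0.0105), from 7.83 ± 0.15 to 6.42 ± 0.32 (log2, SD, n = 3). Of 22 measured members, 1 rose and 1 fell over all genes tested, and 4 rose and 1 fell when adjusted over the list alone, among them Iigp1 (0.58, SE 0.15) and Cxcl10 (0.51, SE 0.15). The list was called higher (median 0.17, or 0.11 without Apc+/- replicate 2, camera adjusted p = 3.25e-07, adjusted p = 0.344 with an estimated correlation).

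Among 14 measured MHC class II presentation genes, H2-Ab1 alone fell over all genes tested, and it had the smallest adjusted p of all genes together with Itln1. H2-Ab1, the beta chain of the class II molecule I-A, fell by 1.32 (SE 0.10, adjusted p = 0.00311), from 10.71 ± 0.09 to 9.39 ± 0.13 (log2, SD, n = 3), a level 2.50 times lower. Adjusted over the list alone, 3 fell, which adds its partner chain H2-Aa (-0.46, SE 0.14) and H2-Ob (-0.38, SE 0.11). The list was called lower (median -0.09, or -0.16 without the male array, camera adjusted p = 9.01e-05, adjusted p = 0.322 with an estimated correlation). Class I-like H2 genes have near-identical copies whose transcripts an array can mix, so the value of H2-Q2 is uncertain in that respect. The value of H2-Ab1 could be affected by differences in H2 gene sequence between the mice, which the array values cannot show.

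Several secreted products of Paneth cells, the antimicrobial cells at the crypt base, fell. Ang4, a microbicidal ribonuclease, fell by 2.49 (SE 0.26, adjusted p = 0.00944), from 9.58 ± 0.59 to 7.09 ± 0.28 (log2, SD, n = 3), which is 5.62 times lower. Itln1, a lectin that binds microbial sugars, fell by 1.24 (SE 0.10, adjusted p = 0.00311), and the defensin Defa24 fell by 1.02 (SE 0.13, adjusted p = 0.0221). Of 15 measured members, 3 fell over all genes tested and 8 when adjusted over the list alone. In neither adjustment did a member rise, while 3 of the 15 were higher without passing. The 8 include lysozyme Lyz1 (-0.78, SE 0.14), the defensin-processing protease Mmp7 (-0.99, SE 0.18) and Mptx1 (-1.99, SE 0.30, adjusted p = 0.0603 over all genes). Defa39, outside the list, fell by 1.42 (SE 0.20, adjusted p = 0.0342), and defensin genes have near-identical copies that the array can mix. The list's call (median -0.45, camera adjusted p = 3.3e-12) was lost with an estimated correlation (adjusted p = 0.18 with an estimated correlation). Fry did not call the list (adjusted p = 0.088). The median was -0.62 and -0.81 with the dimmest genes removed at the looser and stricter limit. It was -0.33 without the male array and -0.59 without Apc+/-Atg7-/- replicate 2.

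**Figure D2:**
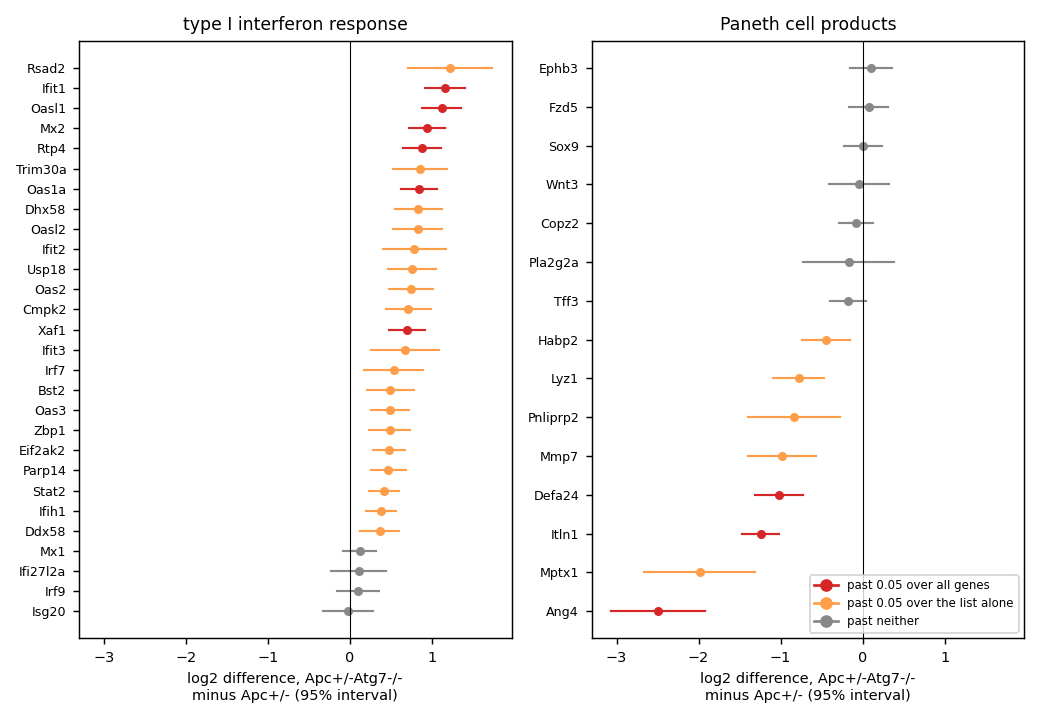
The log2 difference between Apc+/-Atg7-/- and Apc+/- duodenum (horizontal axis) with its 95% interval for each measured member of the type I interferon list (left, 28 genes) and the Paneth cell list (right, 15 genes). Colour gives the test passed, and 24 interferon members lie above 0 and 8 Paneth members below 0 past 0.05 over their list alone.

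Some transcripts of the defence, type 2 effector, goblet cell, tuft cell and pancreatic acinar lists were lower too. Retnlb, a goblet cell product with bactericidal activity, fell by 2.08 (SE 0.22, adjusted p = 0.00944), from 6.86 ± 0.50 to 4.78 ± 0.25 (log2, SD, n = 3). It was the 1 of 28 antimicrobial and defence genes, and the 1 of 20 mast cell and type 2 effector genes, to fall over all genes tested. Adjusted over the list alone, 2 of the defence genes fell, with Reg4 at -0.71 (SE 0.15), as did 3 of the type 2 genes, with the mast cell proteases Mcpt1 (-1.54, SE 0.29) and Mcpt4 (-0.40, SE 0.10). Of 23 genes on the goblet cell list, 0 passed over all genes and 3 fell over the list alone. These were Ccl6 (-0.54, SE 0.09), the membrane mucin Muc3 (-1.04, SE 0.27) and Spink4 (-0.48, SE 0.12). Of 20 tuft cell genes, 0 passed by limma in either adjustment and 18 were lower, among them Rgs13 (-1.03, SE 0.30) and Dclk1 (-0.63, SE 0.17). Clps, a colipase, fell by 1.03 (SE 0.13, adjusted p = 0.0219). It was the 1 of 20 genes on the pancreatic acinar list to pass over all genes, with Rnase1 (-0.77, SE 0.14) the other to fall over the list alone. Values from whole duodenum do not show which cells carried the transcripts of these lists, so a list's name does not give their source. By camera these lists were lower with adjusted p of 0.0256 for defence, 0.00475 for type 2, 0.00857 for goblet, 0.000156 for tuft and 0.000849 for pancreatic acinar genes, and with an estimated correlation the adjusted p was 0.55, 0.322, 0.344, 0.18 and 0.18 in that order. Their medians were small, at -0.099, -0.058, -0.065, -0.156 and -0.077 in the same order. Higher in Apc+/-Atg7-/- duodenum were 9 of 28, 6 of 20, 6 of 23, 2 of 20 and 4 of 20 members. The defence call, on a list whose arrays overlapped, ended without Apc+/- replicate 3 (adjusted p = 0.67) and the goblet call without Apc+/- replicate 1 (adjusted p = 0.098). The type 2 call ended when the dimmest genes were removed (adjusted p = 0.466 and 0.478 at the looser and stricter limit).

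Only 8 genes fell past an adjusted p of 0.05, and the 4 largest other differences with groups apart at an unadjusted p under 0.01 filled the 12 named. Gsdmc2 and Gsdmc4, gasdermins with near-identical copies, differed by -2.51 (SE 0.62, adjusted p = 0.484) and -2.35 (SE 0.56, adjusted p = 0.437), with an SD of 1.60 and 1.37 among the Apc+/- arrays, and stood at -1.61 and -1.56 without Apc+/- replicate 2. Enpp7, the brush border sphingomyelinase, differed by -1.58 (SE 0.32, adjusted p = 0.226), and Mptx1 is the fourth. Both gasdermins belong to the list of 26 apoptosis and necroptosis genes, of which Mlkl rose over all genes, and 1 rose and 2 fell over the list alone. That list was not called (camera adjusted p = 0.297), except lower without Apc+/- replicate 2 (0.0453).

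Nrf2 target genes were called higher as a list. Of 27 measured Nrf2 target genes, 0 passed over all genes by limma and 4 rose when adjusted over the list alone. These were the glutathione transferases Gsta3 (2.07, SE 0.37), Gstm1 (0.83, SE 0.18) and Gsta4 (0.72, SE 0.16) and the quinone reductase Nqo1 (0.68, SE 0.14). Hmox1 (0.02, SE 0.08) and Gclc (-0.15, SE 0.12), from the same list, did not pass. The call (median 0.10, camera adjusted p = 0.00021) was lost with an estimated correlation (adjusted p = 0.55 with an estimated correlation) and without Apc+/- replicate 3 (adjusted p = 0.107, median 0.02). It held without the male array (0.0256) at a median of -0.004 and without Apc+/- replicate 2 at 0.15. The unfolded protein response (camera adjusted p = 0.00545), Atf4 target (0.036) and cholesterol and fatty acid synthesis lists (0.00545) were also called higher with medians of 0.06, 0.07 and 0.07. In these and the Nrf2 list the arrays of the genotypes overlapped. With 1 array left out the medians ran from 0.02 (without Apc+/- replicate 2) to 0.12 (Apc+/- replicate 3), from -0.004 (Apc+/-Atg7-/- replicate 2) to 0.14 (Apc+/- replicate 3) and from -0.03 (Apc+/- replicate 3) to 0.28 (Apc+/- replicate 1). Pdia6 (0.29, SE 0.10), Hyou1 (0.24, SE 0.10), Atf3 (0.36, SE 0.10), Vldlr (-0.21, SE 0.09), Fdps (0.34, SE 0.19) and Acaca (0.32, SE 0.20) had their smallest p, and 0 members passed in either adjustment by limma. Without Apc+/- replicate 3 Fdps and Acaca stood at 0.14 and 0.15, and without Apc+/- replicate 1 at 0.57 and 0.53. With an estimated correlation the adjusted p was 0.55, 0.583 and 0.623. The cholesterol list turned lower without Apc+/- replicate 3 (median -0.03, adjusted p = 0.489) and was not called without Apc+/-Atg7-/- replicate 3 (adjusted p = 0.165). The unfolded protein call ended without Apc+/- replicate 2 (adjusted p = 0.282) or the male array (0.117), the Atf4 call without Apc+/- replicate 1 (0.163), Apc+/- replicate 2 (0.375), Apc+/-Atg7-/- replicate 2 (0.323, median -0.004) or replicate 3 (0.114), and both under a further quantile normalization (0.0676 for each).

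The cell proliferation list was called higher without a member passing. Of 31 proliferation genes, 30 were higher, with a median of 0.28, and 0 passed in either adjustment by limma. Cenpe (0.42, SE 0.12) and Bub1b (0.33, SE 0.09) had the smallest p. The arrays of the genotypes overlapped, with the list's mean deviation at -0.26 to -0.02 in Apc+/- and at -0.04 in the male and above 0.20 in the other 2 Apc+/-Atg7-/- arrays. The camera adjusted p was 2.57e-19, and 0.344 with an estimated correlation. The stem cell list was called at an adjusted p of 0.0377 (median 0.06, adjusted p = 0.55 with an estimated correlation), led by Phlda1 (0.92, SE 0.23) and Cd44 (0.33, SE 0.13), and the call ended without Apc+/- replicate 2 (adjusted p = 0.646, median -0.02), the male array (0.075) or Apc+/-Atg7-/- replicate 3 (0.114, Cd44 0.18), and when arrays were centred on their medians (0.0507). Its arrays overlapped as well, and its median was 0.11 without Apc+/- replicate 3 and 0.09 without the male array. Of 29 Wnt and Myc targets, 0 passed over all genes, Mmp7 fell over the list alone, and the list was not called (camera adjusted p = 0.104), except higher without Apc+/- replicate 3 (0.00814).

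Camera called 6 further lists lower, 5 of cell types and 1 of xenobiotic metabolism, while the arrays of the genotypes overlapped in each. Smooth muscle genes were lower (18 of 20, median -0.30, camera adjusted p = 0.000157, adjusted p = 0.583 with an estimated correlation), with Des at -0.49 (SE 0.19) and Tagln at -0.33 (SE 0.16), but not called without Apc+/-Atg7-/- replicate 2 (adjusted p = 0.291, median -0.07, Des -0.27, Tagln -0.20). Without Apc+/-Atg7-/- replicate 3 the median was -0.48 and Tagln stood at -0.50. Enterocyte and brush border genes were lower (25 of 27, median -0.15, camera adjusted p = 0.000849, adjusted p = 0.55 with an estimated correlation), with Ace at -0.81 (SE 0.28) and Dpp4 at -0.36 (SE 0.14), but not called without Apc+/- replicate 1 (adjusted p = 0.529, median -0.08) or Apc+/-Atg7-/- replicate 3 (adjusted p = 0.161, median -0.07, Ace -0.49, Dpp4 -0.21). Their median was -0.23 without Apc+/-Atg7-/- replicate 2. Xenobiotic metabolism genes were lower (25 of 28, camera adjusted p = 0.00545, adjusted p = 0.588 with an estimated correlation), with Cyp2b10 at -1.34 (SE 0.57) and Cyp2j6 at -0.41 (SE 0.17), but not called without Apc+/- replicate 1 (adjusted p = 0.766) or Apc+/-Atg7-/- replicate 3 (adjusted p = 0.88, Cyp2b10 -0.54, Cyp2j6 -0.19). T cell (24 of 31, adjusted p = 0.00425), B and plasma cell (23 of 25, adjusted p = 0.00371) and fibroblast genes (18 of 21, adjusted p = 0.0409) were lower by camera, with adjusted p of 0.55, 0.55 and 0.588 with an estimated correlation. Xcl1 (-0.33, SE 0.09), Cd27 (-0.29, SE 0.09), Sdc1 (-0.24, SE 0.09), Ccr10 (-0.24, SE 0.11), Fbln1 (-0.61, SE 0.16) and Fbln2 (-0.19, SE 0.09) had their smallest p, and 0 members of these 6 lists passed in either adjustment by limma. The T cell call ended without Apc+/- replicate 1 (adjusted p = 0.855) or the male array (0.269), the B and plasma cell call without Apc+/- replicate 2 (0.248), and the fibroblast call without Apc+/- replicate 2 (0.0992), Apc+/- replicate 3 (0.241), the male array (0.0787) or Apc+/-Atg7-/- replicate 2 (0.378).

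**Figure D3:**
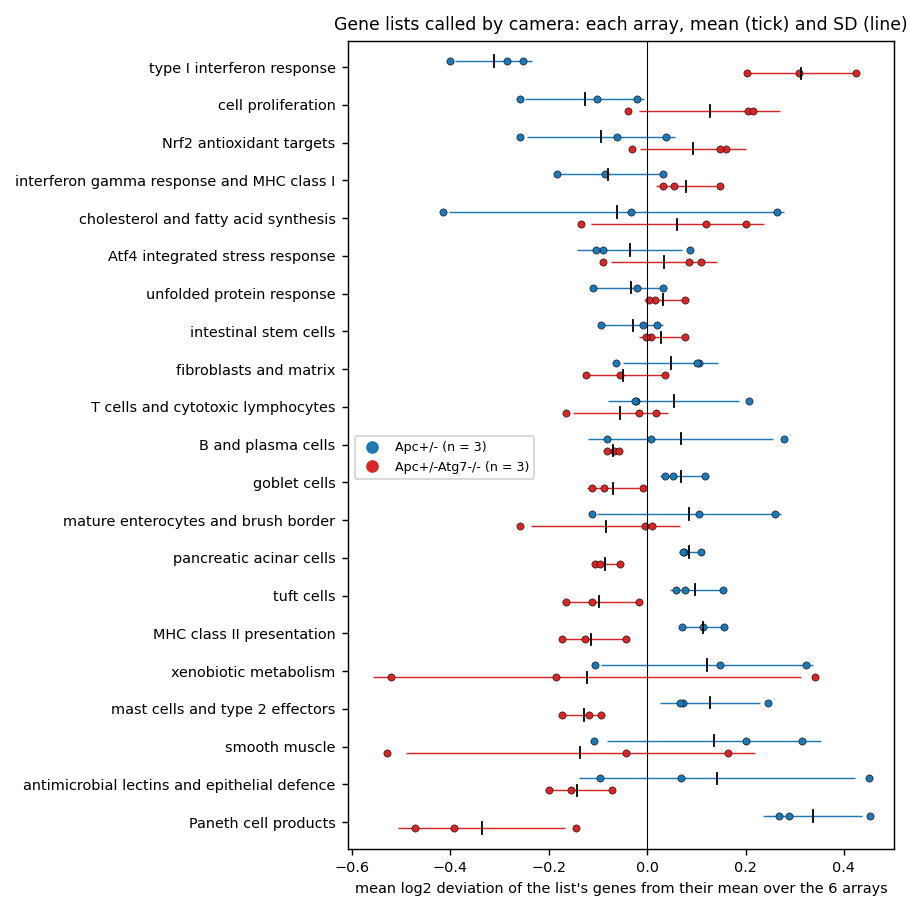
The mean log2 deviation of a list's genes from their mean over the 6 arrays (horizontal axis) for the 21 lists called by camera with a preset correlation, with each array as a point, the group mean as a tick and the SD as a line (n = 3 per genotype). The interferon list lies between -0.40 and -0.25 in Apc+/- and between 0.20 and 0.42 in Apc+/-Atg7-/- arrays, while the arrays of the genotypes overlap in 13 of the 21 lists, the xenobiotic and smooth muscle lists among them.

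In all, 8 lists were called higher and 13 lower by camera with a preset correlation, 0 with an estimated correlation (6 at an unadjusted p under 0.05) and 2 by fry, the second being the pancreatic acinar list (adjusted p = 0.0386). Divisions of the 6 arrays that mix the genotypes gave 11 to 19 calls with the preset correlation, so such a call alone is weak evidence. These divisions still hold part of the difference between the genotypes, so their calls are not a count of false calls. The camera calls of the type I interferon, interferon gamma, class II, Paneth, tuft, type 2, proliferation and pancreatic acinar lists held in each of the 6 fits that left out 1 array, and each of the other 13 was lost in at least 1 of them. Array weights ended the goblet (adjusted p = 0.0633), stem cell (0.0782), Atf4 (0.118), xenobiotic (0.288), T cell (0.288) and enterocyte (0.3) calls, and removal of the dimmest genes ended, besides the type 2 call, those of stem cells (0.0751 and 0.0762) and, at the looser limit, Atf4 targets (0.0717) and defence genes (0.0742). Camera did not call the lists of myeloid cells (adjusted p = 0.0507), lipid absorption (0.0607), enteric neurons and glia (0.0749), regulatory and helper T cell products (0.0785), circadian clock genes (0.111), tight junctions (0.113, up, against a median of -0.01), immediate early and heat shock genes (0.124) or microbial pattern recognition (0.127). Nor did it call adipocytes (0.234), oxidative phosphorylation (0.278), iron handling (0.28), endothelium (0.563), glycolysis (0.598), fatty acid oxidation (0.628), chemokines, cytokines and NF-kB targets (0.652), enteroendocrine cells (0.791), p53 targets (0.791) or Brunner's gland and gastric genes (0.898). Some of these were called in other settings. Myeloid genes were called lower with a variance trend and robust moderation (adjusted p = 0.0432), with the mean of a gene's probe sets (0.0498), with the dimmest genes removed (0.00379 and 0.00093) and without the male array (0.00941), Apc+/- replicate 2 (0.0379) or Apc+/-Atg7-/- replicate 3 (0.0406). Lipid absorption genes were called lower after a further quantile normalization (0.0156), centring (0.0485), with trend and robust moderation (0.0352), at the stricter dim limit (0.0223) and without Apc+/- replicate 3 (2.08e-05), the male array (0.000671) or Apc+/-Atg7-/- replicate 2 (0.0423). Oxidative phosphorylation was called lower after quantile normalization (0.0469) and without Apc+/- replicate 3 (0.00756), as were glycolysis (0.00879) and clock genes (0.00756) without that array, and clock genes (0.00603) without Apc+/-Atg7-/- replicate 2. Iron handling was called higher with array weights (0.0334) and without Apc+/- replicate 1 (0.0107), and immediate early genes (0.00346) and pattern recognition (0.048) without Apc+/-Atg7-/- replicate 2. Without Apc+/-Atg7-/- replicate 3 tight junctions were called higher (0.0171) and regulatory and helper T cell products lower (0.0245), and without the male array fatty acid oxidation lower (0.0442). Erythroid genes, with 3 measured (median -0.01), and sex-linked genes, with 5 (median 1.11, set by the male array), were not tested as lists.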

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

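The gene comparison leaves out probe sets with several symbols or with no entry in the platform annotation, and some of these carried a difference between the genotypes in a test over every probe set. Among probe sets with several gene symbols, 1 was higher and 1 lower in Apc+/-Atg7-/- duodenum past an adjusted p of 0.05 by limma. Among probe sets without an entry, 8 were higher and 7 lower. The largest of these differences was 1.61 (SE 0.22, adjusted p = 0.0427, probe set 10502791), with all 3 Apc+/-Atg7-/- arrays above all 3 Apc+/- arrays. Probe sets 10570656 and 10570676 held identical values on all 6 arrays (-1.02, SE 0.11, adjusted p = 0.0155), as did 10570690 and 10570729 (-1.01, SE 0.11, adjusted p = 0.0155), so the 7 lower ones are not 7 independent signals. Apart from 10351640, the lower ones are numbered from 10570656 to 10570729, as is the lower set with several symbols (10570663). These lie close to the Defa24 probe set 10570735, and whether they are independent of it was not tested. Of the 8 higher ones, 7 are numbered from 10383152 to 10383206, close to the Rnf213 probe set 10383214, and whether they are independent of it was not tested. They were not named, and no explanation was tested for them.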

How the results depend on the processing

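The direction of the 57 genes besides Atg7 that the fixed rule names held in 741 recomputed values (0 reversed), and 82 of these values lost and 14 gained their side of the threshold. Much of the constant direction was fixed in advance. Several settings change only the variance and return the same difference. Most of these genes also have groups that do not overlap, whose sign cannot turn when 1 array is left out. The count of 22 genes past an adjusted p of 0.05 was 0 in the linear model without variance moderation, where 988 genes lay at an unadjusted p under 0.05, since 6 arrays leave few degrees of freedom without the shared variance. It was 39 over every probe set and 2 to 27 when 1 array was left out, with fewer samples in each fit, the 2 being without the male array. With the replicate number as a block it was 44 (22 higher and 22 lower, the reported 22 among them), but the deviations of same-numbered arrays correlated at 0.146, -0.074 and 0.24, not all of them above 0.1, so the numbers were not taken to pair animals. Not every array correlated best with its own number. The block added calls of myeloid cells (0.0311) and lipid absorption (0.00966) and ended that of fibroblasts (0.0505). H2-Ab1 and Itln1 passed in 13 of 14 settings, and Ifit1, Mx2, Oasl1 and Retnlb in 12. The 14 settings include the reported fit and leave out the fits without the dimmest genes and the fit over every probe set. The 741 recomputed values leave out those fits too. The count of 106 genes at 1.5-fold was 62 without moderation, 164 over every probe set, 33 at 2-fold and 88 to 161 with 1 array left out. The 21 lists were 0 with an estimated correlation, whose lowest adjusted p was 0.13, and 2 by fry, and the cause was not tested. With 1 array left out 17 to 22 lists were called. The Atg7 difference stayed between -0.61 and -0.45 with 1 array left out, and its adjusted p between 0.0878 and 0.879 over the same 14 settings. Centring the arrays turned the sign of the median of 7 lists and a further quantile normalization that of 2, all of them lists that were not called. The signal over background of single probe sets was not used here, so for dim genes a small difference is only not detectable.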

Other observations

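Several transcripts outside the lists showed differences of a size that limma did not call over all genes. Nox1, the epithelial NADPH oxidase, averaged 5.95 ± 0.47 in Apc+/- and 7.89 ± 1.08 in Apc+/-Atg7-/- duodenum (log2, SD, n = 3, adjusted p = 0.363), and the acyltransferase Mboat1 differed by 1.47 (SE 0.28, adjusted p = 0.174). Klrb1, a lectin-like receptor of lymphocytes, was lower by a log2 difference of -1.08 (SE 0.19, adjusted p = 0.146) and the IgA heavy chain Igha differed by -0.72 (SE 0.14, adjusted p = 0.218). In each of these 4 the arrays of the genotypes did not overlap, as in 10% of genes by chance. They were picked after their values were seen.

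Further H2 genes went both ways. H2-Bl differed by -1.14 (SE 0.21, adjusted p = 0.167) and H2-M2 by -0.61 (SE 0.13, adjusted p = 0.284), while H2-Ea differed by 0.49 (SE 0.09, adjusted p = 0.17), from 10.49 ± 0.11 to 10.98 ± 0.04 (log2, SD, n = 3). None of these passed by limma, and they were picked after their values were seen.

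Of the tests in this part, those of infiltrating cells, the male array, the type 2 response and class II presenting cells were chosen after the results were seen. The 6 arrays divide into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 22 genes past an adjusted p of 0.05 against at most 1 in any other. It gave 106 genes at 1.5-fold against 9 to 79, and 21 lists against 11 to 19 in the others. In each case 1 of the 10 reached the real count. Every division that mixes the genotypes gave at least 11 list calls, so the number of called lists says little about the genotypes. Such a division still sets unequal numbers of each genotype against each other. Its calls can therefore hold part of the real difference and are not a count of false calls.

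A higher type I interferon response is a hypothesis for the genes that rose. More infiltrating T cells and myeloid cells would raise their markers, but the mean difference of 62 such markers that are not on the interferon lists was -0.091 (SE 0.044). The single male array does not account for the rise, since the list's mean difference was 0.568 (SE 0.069) without it and 0.624 (SE 0.078) with it. Which cells carry the response, and whether the microbiota or housing differed between the genotypes, stays open and was not tested.

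The fall of Paneth cell products may reflect fewer Paneth cells, less product per cell or less of a type 2 response that induces some of them. Fewer cells and less product per cell both lower the products, and comparisons of single products, tried after their values were seen, were dropped because probe sets differ in how far they compress a change, so that question was left without a test. For the type 2 response, tuft cell markers were lower by a mean log2 difference of -0.194 (SE 0.052), but not by camera with an estimated correlation (adjusted p = 0.18). That form of camera called 0 of the 43 lists, with a lowest adjusted p of 0.13. Its lack of a call for tuft markers therefore decides nothing, and the question stays open.

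The lower H2-Ab1 could come from fewer cells that present antigen on MHC class II, and the 13 other measured members of the class II list were lower by a mean log2 difference of -0.144 (SE 0.045) against -1.32 for H2-Ab1. As for the Paneth cell products, unequal sizes do not decide it, so this stays open, and an earlier comparison with 4 of the 13, picked after their values were seen, was dropped. A variant haplotype of the H2 region that differs between the genotypes would change probe binding or expression of neighbouring genes, and 1 of 91 neighbours not named H2 (Btnl2) lay at an unadjusted p under 0.01, 1.1% against 1.2% elsewhere (Fisher's exact test, one-sided p = 0.668). At 1.2% so few are expected among 91 genes that the test neither shows nor rules out such a haplotype. Differences in H2 gene sequence between the mice, which the array values cannot show, stay open. For class I-like genes such as H2-Q2, signal shared between near-identical copies stays open too.

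As a check for a passenger segment around the targeted Atg7 allele, 1 of the 100 genes next to Atg7 (Pparg, 0.53) lay at an unadjusted p under 0.01, 1% against 1.23% elsewhere (Fisher's exact test, one-sided p = 0.711), which neither shows nor rules out such a segment.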
